A study of Mus musculus with 16 samples.

How the data were processed

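Poly(A) RNA-seq libraries came from sorted MSCs and sorted osteoblasts of 4 wild-type and 4 miR-9-1-deficient mice, 16 libraries in 4 groups of 4. The labels give the genotype, the cell type and an animal number but no sort gate, sex or age. The deposited unit is a normalized count per gene symbol, and the submitters' processing notes name DESeq2 1.24.0 and the mm10 build. Every deposited signal value in a library was a whole multiple of 1 step, so the authors' values are gene counts divided by 1 size factor per library (100% of values were whole within 0.01 after multiplying back). The aligner, counting program, annotation and filters are not given in the sources used here. The table held 20056 symbols.

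Whole reads were recovered from these values. MSC libraries held 10148197 to 14246986 reads and OB libraries 15543693 to 18962771, with size factors from 0.665 to 0.852 and from 1.27 to 1.54. A library with 0 reads of a gene allows up to 3 reads at 95% confidence, which is 3.52 to 4.51 normalized counts in MSCs and 1.95 to 2.36 in OBs. Counting error alone understates the spread between mice: replicate pairs had a chi-square per degree of freedom of 10.3 to 128. The ribosomal RNA precursor Rn45s took 0.555 to 2.46% of reads.

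Values were analysed as log2(normalized count + 1) with limma 3.58.1 (linear model, empirical Bayes with trend) in R 4.3.3, over genes with a value of 10 or more in at least 4 of the libraries fitted. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were miR-9-1-deficient against wild-type within MSCs and within OBs (8 libraries each), wild-type OBs against wild-type MSCs (8 libraries), and the difference of the genotype effects, OBs minus MSCs (16 libraries). Of 33 gene lists, fixed before the data were examined, 2 had no gene tested (mitochondrially encoded genes and miR-9 loci), the X- and Y-linked list served only as a check of the animals, and 30 were tested. Each was tested with limma camera, at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, which asks whether a list's genes move on balance in 1 direction. List p-values were adjusted over the lists of a comparison.

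The correlation of the genotype effects was tested by moving genotype over the 8 mice, with both libraries of a mouse kept together. Seed sites of miR-9-5p were searched in the longest annotated 3′ UTR of each gene (GRCm38/mm10), genes without a site were matched on UTR length in 10 bins, and genotype was permuted exactly within a cell type (70 relabellings, smallest two-sided p 0.0286). Genes without an annotated 3′ UTR counted as not searched. Coordinates are on GRCm38/mm10.

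The animal numbers are the same in both cell types and were taken to name the same mice. Deviations from the group means of the MSC and OB libraries of a mouse correlated with r from 0.0241 to 0.285, and 7 of 8 numbers correlated best with their own. The fit with the mouse as a replicate block was the alternative for the comparison of cell types and for the difference of effects.

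Genes were named by a rule written before the data were examined. Per direction it takes the 10 passing genes with the largest change among those with a mean of at least 50 and no overlap between groups (overlap is not asked for the difference of effects). Where fewer than 10 pass, it takes those and then the smallest p up to 5 in that direction. It also takes up to 4 passing members of each list per direction, or up to 2 with the smallest p, and 20 genes fixed by name, the miR-9 loci and the X- and Y-linked genes. The rule gave 90 genes in MSCs, 89 in OBs, 216 between cell types and 89 for the difference of effects. All genes it took other than as list members are named (43, 34, 44 and 34). Of those taken only as list members (47, 55, 172 and 55), the text names 26, 5, 25 and 6, chosen for length after their values were seen, and some are not reported here. Phospho1, Fmo1 and Cytl1 lie outside the rule in MSCs and were named because they passed in OBs.

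Alternatives written before the data were examined were a pseudocount of 5, no filter, a filter of 50, quantile normalization, array weights, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on recovered reads, an absolute log2 fold change of 1 or more, a blood-cell covariate, all 16 libraries in 1 fit with and without the mouse as a random term, the series of animal numbers, the replicate block and leaving out each library. The code was tested on simulated data with known changes. Of simulated 2-fold changes, 28.3% passed in MSCs, 55.2% in OBs, 66.7% between cell types and 19.7% for the difference of effects. Of 1.5-fold changes, 4.88%, 27.7%, 38.7% and 1.56% passed. A gene that did not pass may thus still differ by 2-fold. Mir9-1 was too low to test, and protein, isoforms and mature microRNAs were not measured in these libraries.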

Results

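Poly(A)-selected RNA was sequenced from sorted mesenchymal stem cells (MSCs) and sorted osteoblasts (OBs) of 8 mice, 4 wild-type and 4 in which the microRNA locus Mir9-1 had been disrupted by CRISPR/Cas9 editing (miR-9-1-deficient). By the animal numbers in the labels, each mouse gave 1 MSC and 1 OB library, so the 16 libraries fell into 4 groups of 4. Every OB library held both the X-inactivation transcript Xist and the Y-linked gene Ddx3y. Its RNA may therefore not come from 1 mouse alone, and the independence of the 4 OB libraries of a group is not established. MSC libraries held 10148197 to 14246986 recovered reads and OB libraries 15543693 to 18962771. The study asked how miR-9-1 acts in the bone marrow niche in which lymphocytes form. Values are normalized counts as mean ± SD (n = 4). Log2 fold changes carry their standard error and were taken on the log2(value + 1) scale, which understates the change of low genes. Adjusted p-values are from limma unless another tool is named. Mice are lettered in the order of the labels, A to D wild-type and E to H miR-9-1-deficient, with the same letter for both libraries of a mouse.

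Mir9-1 (chromosome 3, 88215598 to 88215686, plus strand, GRCm38/mm10, a microRNA gene) was read at a very low level. Of the 4 wild-type OB libraries, B held 16 reads (normalized count 10.4), A held 7 (5.50), D held 4 (2.94) and C held 0. Of the 4 miR-9-1-deficient OB libraries, F held 3 reads (1.95), and E, G and H held 0. All 8 MSC libraries held 0 reads, which allows up to 3.52 to 4.51 normalized counts, against 1.95 to 2.36 in OB libraries. These limits cover counting error only. The gene was below the filter and was not tested, so the loss of Mir9-1 was not detectable in MSCs at this depth. Mir9-3 held at most 3 reads in any library, and A330076H08Rik, a non-coding gene listed with the miR-9 loci, lay between 0 and 37.6 normalized counts.

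In MSCs, the lists of bone matrix, B-cell and antigen presentation genes were lower in miR-9-1-deficient mice by camera with its preset correlation. With an estimated correlation these calls were lost (adjusted p = 0.513, 0.508 and 0.513), and 5 of 34, 4 of 18 and 1 of 16 members passed on their own. Whether the B-cell reads came from MSCs or from B-lineage cells in the sorts was not tested. Among the genes that passed, the opioid precursor Penk was higher. Penk (chromosome 4, 4133531 to 4138819, minus strand), which encodes proenkephalin, rose by 2.93 ± 0.28 on the log2 scale, from 588 ± 112 to 4756 ± 1902 (adjusted p = 0.00566). Bglap (chromosome 3, 88383501 to 88384464, minus strand), which encodes osteocalcin, changed by -4.67 ± 0.57, from 378 ± 159 to 18.0 ± 19.0 (adjusted p = 0.0167). Rag1 (chromosome 2, 101638282 to 101649501, minus strand), the V(D)J recombinase of developing lymphocytes, changed by -5.22 ± 0.88, from 114 ± 32.2 to 4.08 ± 5.07 (adjusted p = 0.0285), with the deficient mean close to the floor of 3 reads. Igf1, a growth factor of the niche, fell from 4152 ± 924 to 1399 ± 587 (-1.64 ± 0.27, adjusted p = 0.0269).

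**Figure D1:**
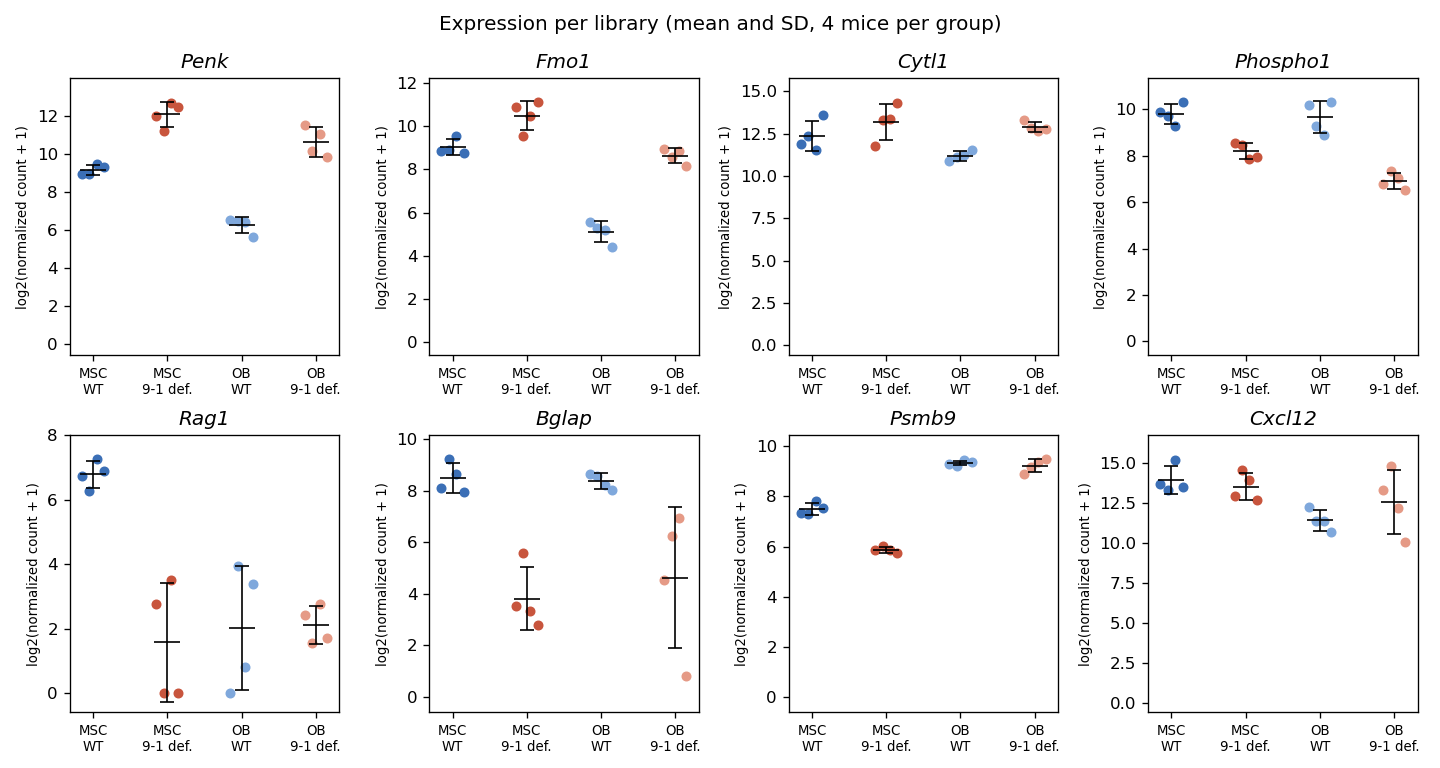
Expression of 8 genes in each library, as log2(normalized count + 1), for the 4 groups (9-1 def. is miR-9-1-deficient). Points are libraries, and the bars give the mean and SD of 4 mice. Penk lies higher and Phospho1 lower in all 4 deficient libraries than in all 4 wild-type libraries of either cell type.

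Among the genes that the naming rule took for the largest increase in MSCs, Cxcl13 (chromosome 5, 95956951 to 95961068, plus strand), a chemokine that attracts B cells, was at 0 in all 4 wild-type libraries and at 206 ± 166 in the deficient ones, which is at least 49.7-fold higher than the mean floor of 3 reads per library (adjusted p = 0.0167). The transcript 4833403I15Rik rose by 4.20 ± 0.61. The steroid sulfate transporter gene Slc10a6 rose by 3.87 ± 0.61, from 48.1 ± 21.2 to 865 ± 605, and Inmt, a methyltransferase gene, by 3.67 ± 0.75. The transcription factor genes Klf15 and Zbtb16 rose by 3.63 ± 0.64 and 3.01 ± 0.54. The glycosylation enzyme gene Galnt15 rose by 3.28 ± 0.56, Fkbp5, a co-chaperone of the glucocorticoid receptor, by 2.82 ± 0.42 (from 455 ± 108 to 3899.8 ± 3005), and the protease inhibitor gene Serpina3n by 2.81 ± 0.47. Their adjusted p-values lay between 0.0253 and 0.0457. Fmo1, a flavin monooxygenase gene outside the naming rule, rose by 1.47 ± 0.31 (adjusted p = 0.0496).

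Among the genes with the largest decrease in MSCs, Bglap2 changed by -4.50 ± 0.75, and its reads and those of Bglap are uncertain, since these neighbours are near-identical copies. Kera, a small proteoglycan gene, changed by -4.00 ± 0.65 (from 1892 ± 426 to 188 ± 202), Spon2 by -3.83 ± 0.67, and the B-cell transcription factor gene Spib by -3.0 ± 0.56. Col15a1, a basement-membrane collagen gene, changed by -3.0 ± 0.60, Lair1, a collagen-binding inhibitory receptor gene, by -2.77 ± 0.52, Cilp2, a cartilage matrix gene, by -2.63 ± 0.46, and Cacna2d3, a calcium channel subunit gene, by -2.59 ± 0.53. Phospho1, a mineralization enzyme gene outside the naming rule, fell from 918 ± 262 to 299 ± 71.6 (-1.60 ± 0.24, adjusted p = 0.0253).

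Of 14964 genes tested in MSCs, 159 passed an adjusted p of 0.05 in limma, 75 higher and 84 lower in miR-9-1-deficient mice. At an unadjusted p under 0.05 there were 3405. The groups did not overlap for 12.4% of the genes tested, against 2.86% by chance. DESeq2 called 1196 genes, and edgeR with its own scaling called 147, of which 87 were higher and 60 lower, a share of 59.2% higher against 47.2%. The count rested on single libraries: it was 12 without wild-type A, 0 without wild-type B (2731 unadjusted), 6 without wild-type C, 1 without wild-type D, 11 without deficient E, 2261 without deficient F, 1 without deficient G and 2 without deficient H. Reads of skeletal muscle genes moved with 2 deficient libraries: the mean log2 level of that list was 6.12 in G and 7.80 in H, against 3.19 to 4.49 in the other MSC libraries. In limma 0 genes passed with this level as a covariate (2725 unadjusted) or without both libraries (1942 unadjusted). Penk was at 2.62 ± 0.29 with the covariate and at 2.44 ± 0.26 without both libraries, against 2.93 ± 0.28 in the main fit. Of the passing genes, 159 of 159 and 158 of 158 kept their direction. They were chosen by passing in these same libraries, so this count does not test an effect of muscle reads. The median standard error of these genes went from 0.24 to 0.28 and 0.30. Without deficient F, 9 genes given below as not passing passed: Foxo3, Spp1, Sp7, Alpl, Col11a1, Col9a1, Oas2, Laptm5 and Mpeg1 (adjusted p from 0.00398 to 0.0481). Penk did not pass without wild-type B (adjusted p = 0.0518) and ranged from 3.97e-22 to 0.0909 over its alternatives.

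The list of osteoblast and bone matrix genes was lower in deficient MSCs, with a median log2 fold change of -0.95 over 34 genes (camera adjusted p = 1.1e-08, adjusted p = 0.513 with an estimated correlation). In this list 0 genes were higher and 5 lower over all genes tested, and 1 higher and 18 lower adjusted over the list alone. Cpz, a carboxypeptidase gene, fell from 243 ± 68.2 to 59.5 ± 25.4, and Smpd3, a mineralization enzyme gene, from 1072 ± 783 to 239 ± 79.9. Beside these, Bglap, Bglap2 and Phospho1, the following members fixed by name did not pass: the collagen gene Col1a1 (-1.38 ± 0.54, adjusted p = 0.165), the alkaline phosphatase gene Alpl (-0.96 ± 0.37, adjusted p = 0.160), the osteoblast transcription factor genes Sp7 (-0.91 ± 0.34, adjusted p = 0.147) and Runx2 (-0.36 ± 0.19, adjusted p = 0.274), and Spp1, which encodes osteopontin (0.95 ± 0.30, adjusted p = 0.111). Col1a1 was at -0.20 with quantile normalization (adjusted p = 0.807) and passed with DESeq2 (-1.25, adjusted p = 0.00105).

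Collagen and other matrix genes were lower with a median of -0.76 over 36 genes (camera adjusted p = 1.58e-05, adjusted p = 0.513 with an estimated correlation), with 1 higher and 5 lower over all genes and 3 higher and 19 lower adjusted over the list alone. Mfap4, a microfibril gene, fell from 4981 ± 1615 to 1112 ± 397, Col8a1 from 13009 ± 3748 to 4107 ± 1130.4 and the collagen cross-linking gene Loxl2 from 7550.0 ± 1125 to 3161 ± 1341, while Fbln2, which encodes fibulin-2, rose from 5859 ± 1097 to 10322 ± 1354. Cartilage genes had a median of -1.22 over 19 genes (camera adjusted p = 1.84e-05, adjusted p = 0.571 with an estimated correlation), with 0 passing over all genes in limma and 0 higher and 5 lower adjusted over the list alone. Col11a1 (-1.43 ± 0.30, adjusted p = 0.0517) and Col9a1 (-2.57 ± 0.56, adjusted p = 0.0551) lay just over the threshold.

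B-lineage genes were lower in all 18 members tested, with a median of -1.65 (camera adjusted p = 9.63e-11, adjusted p = 0.508 with an estimated correlation). Of them 4 passed over all genes, and adjusted over the list alone 0 higher and 16 lower passed. The fry test, which asks whether a list's genes move on balance in 1 direction, gave an adjusted p of 0.00752. Cd79b, part of the B-cell receptor, fell (-1.67 ± 0.30, adjusted p = 0.0373). Vpreb3, a pre-B-cell receptor gene, stood at 53.3 ± 23.0 in wild-type mice and at 1.71 ± 2.02, under the floor, in deficient mice (adjusted p = 0.0410). The libraries do not tell whether reads of these B-lineage genes came from MSCs or from B-lineage cells in the sorts. Blood-cell RNA was present: neutrophil, erythroid and macrophage genes had mean log2 levels of 9.62, 7.55 and 7.45 in wild-type MSC libraries. The decreases of Rag1, Spib, Cd79b and Vpreb3 may therefore mark fewer B-lineage cells in the deficient sorts rather than a change within MSCs. Antigen presentation genes had a median of -0.47 (camera adjusted p = 1.33e-04, adjusted p = 0.513 with an estimated correlation), and the immunoproteasome gene Psmb9 fell from 181 ± 30.1 to 58.0 ± 4.87 (-1.61 ± 0.26, adjusted p = 0.0268). Interferon-response genes had a median of -0.67 over 29 genes (camera adjusted p = 4.67e-04, adjusted p = 0.513 with an estimated correlation), with 0 passing over all genes in limma and 1 higher and 11 lower adjusted over the list alone. Oas2 (-1.98 ± 0.46, adjusted p = 0.0608), an antiviral enzyme gene, did not pass. Macrophage and monocyte genes had a median of -0.65 (camera adjusted p = 0.00521, adjusted p = 0.599 with an estimated correlation), with Laptm5 (-0.83 ± 0.20, adjusted p = 0.0669) and Mpeg1 (-1.56 ± 0.42, adjusted p = 0.0819) not passing. This call was lost without wild-type C (adjusted p = 0.0819) or without deficient F (adjusted p = 0.134; 8.79e-06 to 0.134 over the libraries left out).

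Of the lists that were higher in deficient MSCs, ribosomal protein genes had a median of 0.36 over 82 genes (camera adjusted p = 1.21e-20, adjusted p = 0.508 with an estimated correlation), with 2 higher over all genes and 60 higher and 1 lower adjusted over the list alone. Rps27 rose from 2965 ± 136 to 4977 ± 902 and Rpl37a from 1933 ± 127 to 2865 ± 202. Immediate early and stress genes had a median of 0.28 (camera adjusted p = 1.58e-05, adjusted p = 0.508 with an estimated correlation), and the transcription factor gene Myc rose from 3036 ± 602 to 6432 ± 1222. Skeletal muscle genes had a median of 1.29 over 11 genes (camera adjusted p = 0.0244, adjusted p = 0.602 with an estimated correlation), with Ckm, a creatine kinase gene, not passing (3.66 ± 1.29, adjusted p = 0.134). The call was lost without deficient G (adjusted p = 0.0617) or without deficient H (adjusted p = 0.344; 6.4e-05 to 0.344 over the libraries left out). Cell cycle genes were lower with a median of -0.41 (camera adjusted p = 1.56e-04, adjusted p = 0.599 with an estimated correlation), and Top2a, a DNA topoisomerase gene, fell from 1301 ± 173 to 689 ± 154. Genes of the secretory pathway and the unfolded protein response had a median of -0.55 (camera adjusted p = 1.84e-05, adjusted p = 0.513 with an estimated correlation), with 0 higher and 12 lower adjusted over the list alone, and Manf, an endoplasmic reticulum stress gene, fell from 2072 ± 208 to 1107 ± 348.

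In all, 12 of 30 lists passed camera in MSCs, 3 higher and 9 lower. With an estimated correlation 0 passed, 2 at an unadjusted p under 0.05, and fry called 3. Of the niche factors, 29 were tested, and Igf1 and Ptn, which encodes pleiotrophin, were lower over all genes (-1.98 ± 0.41, adjusted p = 0.0477 for Ptn). The list itself did not pass (median -0.26, camera adjusted p = 0.261, adjusted p = 0.599 with an estimated correlation), and its median was -0.16 without wild-type C, -0.14 without deficient E and -0.41 without deficient F. The chemokine gene Cxcl12 (-0.40 ± 0.47, adjusted p = 0.639), the lymphoid cytokine genes Il7 (-0.90 ± 0.45, adjusted p = 0.255) and Flt3l (-0.35 ± 0.34, adjusted p = 0.565), Kitl, which encodes stem cell factor (0.17 ± 0.27, adjusted p = 0.730), Tnfsf11, which encodes RANKL (-0.44 ± 0.30, adjusted p = 0.401), Csf1 (-0.22 ± 0.24, adjusted p = 0.612) and the leptin receptor gene Lepr (-0.24 ± 0.25, adjusted p = 0.603) did not pass. Neither did Foxo1 (0.20 ± 0.21, adjusted p = 0.597), Foxo3 (0.80 ± 0.18, adjusted p = 0.0555), Runx1 (0.0982 ± 0.16, adjusted p = 0.744), Rest (0.12 ± 0.21, adjusted p = 0.766) and Hes1 (-0.00368 ± 0.16, adjusted p = 0.992). Single members of other lists passed: Cebpd (1.46 ± 0.26) and Ndrg1 (0.81 ± 0.14) higher, and Thy1 (-2.03 ± 0.34), Acp5 (-1.66 ± 0.35) and Ltbp1 (-1.06 ± 0.14) lower. Onecut2 was below the filter.

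**Figure D2:**
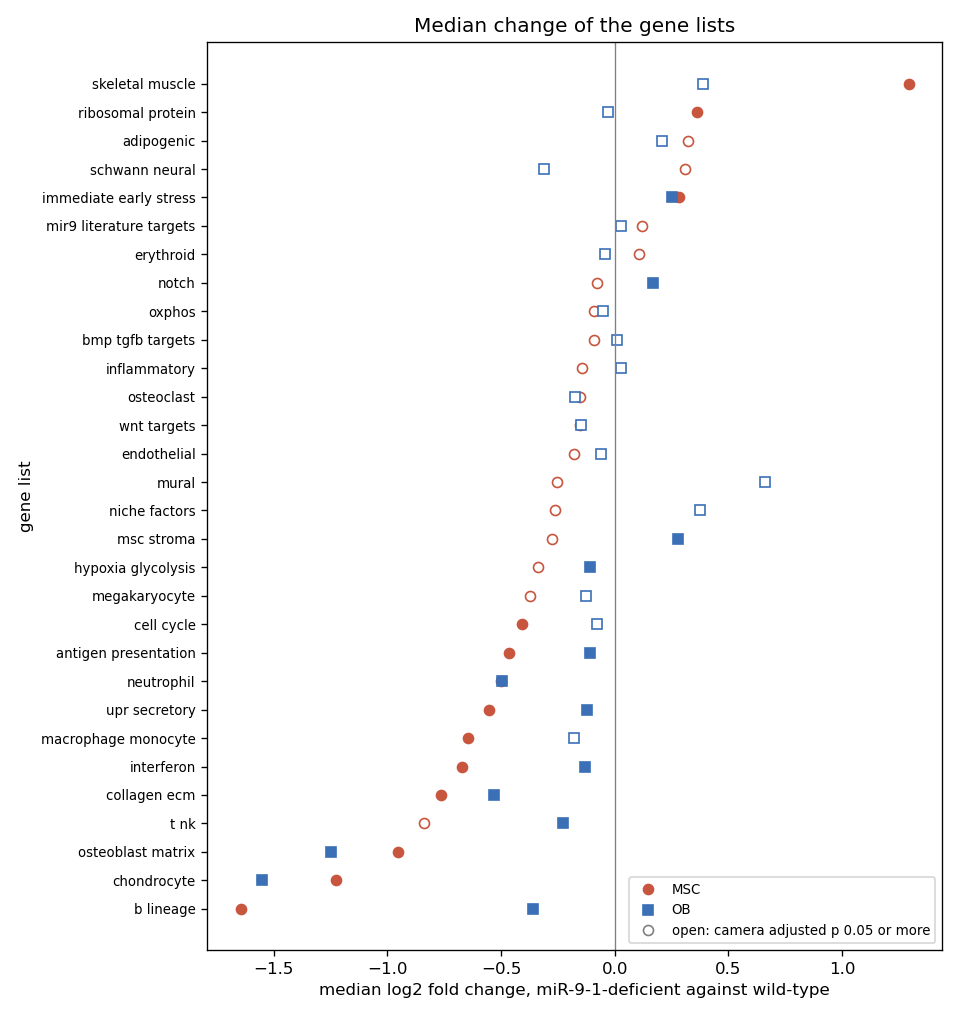
Median log2 fold change of each gene list, miR-9-1-deficient against wild-type, in MSCs (circles) and OBs (squares). Filled symbols mark lists past an adjusted p of 0.05 in camera with its preset correlation. Osteoblast matrix genes had medians of -0.95 in MSCs and -1.25 in OBs.

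In the OB libraries, 4 genes passed between genotypes. These libraries held Xist and Ddx3y together, and 19 of 22 blood progenitor genes lay above every MSC library. Bone matrix genes had a median log2 fold change of -1.51 in wild-type OBs against wild-type MSCs. The genotype values below are thus those of the OB libraries, and how far they come from osteoblasts was not tested. Penk rose by 4.37 ± 0.36, from 79.0 ± 19.99 to 1797 ± 957 (adjusted p = 0.00269), and Fmo1 by 3.53 ± 0.27, from 35.2 ± 10.8 to 409 ± 96.9 (adjusted p = 0.00269). Cytl1, which encodes a secreted protein of cartilage, rose by 1.69 ± 0.16, from 2383 ± 474 to 7696 ± 1630.2 (adjusted p = 0.00814). Phospho1 (chromosome 11, 95824499 to 95832140, plus strand), a phosphatase gene of matrix mineralization, changed by -2.74 ± 0.31, from 879 ± 389 to 123 ± 29.4 (adjusted p = 0.0244). Penk, Fmo1 and Phospho1 passed in MSCs too, and Cytl1 did not (0.84 ± 0.52, adjusted p = 0.355), although none of these genes passed the test of the difference between the cell types.

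Of 14229 genes tested in OBs, these 4 passed in limma, and 1274 did at an unadjusted p under 0.05. The groups did not overlap for 5.47% of the genes tested, against 2.86% by chance. The same limma test with quantile normalization called 16 genes, 9 higher and 7 lower (56.3% higher against 75.0%). edgeR called 4 and DESeq2 194 (58.8% higher). The count was 7 without wild-type C (5 higher), 20 without deficient E (13 higher), 30 without deficient F (6 higher) and 108 without deficient H (87 higher). Genes of the MSC stroma list were at a mean log2 level of 9.45 in deficient E and 9.88 in deficient F, against 7.50 to 8.92 in the other OB libraries. In limma 252 genes passed with this level as a covariate (90 higher) and 88 without both libraries (17 higher). Phospho1 did not pass without wild-type A (adjusted p = 0.10), B (0.0599) or D (0.0908) or deficient G (0.117), and ranged from 1.71e-10 to 0.117 over its alternatives. Cytl1 did not pass without wild-type B (adjusted p = 0.0531) and ranged from 9.36e-11 to 0.187.

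Genes next in order of p did not pass. Upwards these were Galnt15 (4.18 ± 0.63, adjusted p = 0.0874) and the cold-inducible RNA-binding gene Cirbp (0.40 ± 0.0602, adjusted p = 0.0874), and downwards Arsi (-4.48 ± 0.59, adjusted p = 0.0665), Abi3 (-2.02 ± 0.28, adjusted p = 0.0742), the cartilage collagen gene Col2a1 (-2.89 ± 0.40, adjusted p = 0.0765) and Syt8 (-2.38 ± 0.36, adjusted p = 0.0874). Abi3 (chromosome 11, 95830074 to 95842476, minus strand) overlaps Phospho1 on the other strand. The counting program is not given, so reads in the shared stretch may belong to either gene. Klf15 had a log2 fold change of 3.71 ± 0.66, adjusted p = 0.112. These genes passed in some alternatives: Arsi in 13 of 19, and of 23 Abi3 in 11, Galnt15 in 10, Syt8 in 9, Col2a1 in 8, Klf15 in 7 and Cirbp in 5. With 1 library left out, Galnt15, Cirbp, Arsi, Abi3, Col2a1 and Syt8 passed without deficient H (adjusted p from 0.0199 to 0.0372). Without deficient F, Galnt15, Arsi, Abi3 and Klf15 did (0.0134 to 0.0497), without deficient E, Arsi, Col2a1, Syt8 and Klf15 (0.0347 to 0.0430), and without wild-type C, Abi3 (0.0300). Osteoblast and bone matrix genes were lower in deficient OBs with a median of -1.25 over 35 genes (camera adjusted p = 7.83e-14, adjusted p = 0.544 with an estimated correlation), with 1 lower over all genes and 1 higher and 21 lower adjusted over the list alone. Col1a1 (-2.38 ± 0.52, adjusted p = 0.204), Bglap (-3.74 ± 1.1, adjusted p = 0.361), Alpl (-1.49 ± 0.55, adjusted p = 0.446), Sp7 (-0.84 ± 0.39, adjusted p = 0.564), Spp1 (0.66 ± 0.46, adjusted p = 0.688) and Runx2 (-0.0793 ± 0.12, adjusted p = 0.871) did not pass over all genes. Col1a1 passed without deficient H (-1.82, adjusted p = 0.0357), with DESeq2 (-2.11, 0.00322), with the mouse as a random term (0.0488) and with the stromal covariate (-2.64, 0.00518). Cartilage genes had a median of -1.55 over 20 genes (camera adjusted p = 1.8e-11, adjusted p = 0.544 with an estimated correlation), with 0 over all genes in limma and 0 higher and 12 lower adjusted over the list alone. Collagen and matrix genes had a median of -0.53 (camera adjusted p = 0.00367, adjusted p = 0.705 with an estimated correlation), with Col11a1 (-2.12 ± 0.38, adjusted p = 0.112) and Col15a1 (-2.92 ± 0.50, adjusted p = 0.103) not passing. This list was lost without deficient H (adjusted p = 0.616; 2.13e-08 to 0.616 over the libraries left out). Of 23 alternatives Col11a1 passed in 7, among them without deficient H (adjusted p = 0.0425), and Col15a1 in 7, among them without deficient F (0.00222). The list median was -0.18 without H, -0.97 without F and -1.40 without both E and F.

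Immediate early and stress genes were higher, 29 of 30 of them positive, with a median of 0.25 (camera adjusted p = 8.59e-07, adjusted p = 0.544 with an estimated correlation). The heat shock genes Hspa1a (0.75 ± 0.29, adjusted p = 0.477) and Dnaja1 (0.17 ± 0.0700, adjusted p = 0.521) did not pass. Genes of the MSC stroma list had a median of 0.28 (camera adjusted p = 0.0251, adjusted p = 0.705 with an estimated correlation), beside the 2 libraries with high levels of that list. The call was lost without wild-type C (adjusted p = 0.0680), wild-type D (0.0609), deficient E (0.323) or deficient F (0.643), with a range of 2.24e-08 to 0.643 over the libraries left out. Altogether 13 of 30 lists passed camera in OBs, 3 higher and 10 lower. With an estimated correlation 0 passed (0 at an unadjusted p under 0.05), and fry called 0 (5 unadjusted). The number of lists was 7 without wild-type C and 20 without deficient H.

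Of the 20 genes fixed by name, 19 were tested in OBs and none passed (adjusted p from 0.204 to 0.948). The niche cytokine genes gave Cxcl12 1.16 ± 0.83, Kitl 1.53 ± 0.66, Il7 0.41 ± 0.49, Igf1 -0.62 ± 0.51, Flt3l -0.20 ± 0.22, Tnfsf11 0.68 ± 0.71, Csf1 0.62 ± 0.39 and Lepr 1.2 ± 0.73 on the log2 scale. The regulators gave Runx1 0.11 ± 0.0540, Foxo1 0.0275 ± 0.0911, Foxo3 0.13 ± 0.0845, Rest -0.12 ± 0.0870 and Hes1 0.0469 ± 0.12. The niche factor list had a median of 0.37 and did not pass (camera adjusted p = 0.211, adjusted p = 0.773 with an estimated correlation). The median was 0.15 without deficient E, 0.21 without deficient F and -0.25 without both, with 19 of 28 genes negative.

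The genotype effects in MSCs and OBs were compared across genes. Over 13863 genes tested in both, the correlation across genes was r = 0.480 (exact permutation of genotype over the 8 mice, two-sided p = 0.0571; Spearman rho = 0.442, exact permutation p = 0.0857). Genes are not independent replicates. Of 35 splits of the mice, 2 gave a correlation as large, the real one included, and the highest of the others was 0.493. Of the 152 MSC genes past the threshold that were tested in OBs, 142 (93.4%) moved in the same direction, and the highest other split gave 92.9%. Leaving out mouse E (r = 0.419) or F (r = 0.542) gave an exact permutation p of 0.0286, the smallest these permutations allow. It was 0.0571 without A (r = 0.472) or C (r = 0.4996), 0.0857 without D (r = 0.467) or G (r = 0.453), 0.114 without B (r = 0.440) and 0.143 without H (r = 0.409) or with a filter of 50 (r = 0.559).

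The wild-type OB libraries were compared with the wild-type MSC libraries. Every OB library held Xist and Ddx3y together, and 19 of 22 blood progenitor genes were above every MSC library, so the comparison is one of libraries. By camera with its preset correlation, lists of stromal matrix, niche and mural genes were lower in OBs and lists of cell cycle, erythroid and ribosomal protein genes were higher. With an estimated correlation 0 of 30 lists passed (6 unadjusted; adjusted p from 0.186 to 0.407 for these lists), and fry called 23. Cxcl12 fell from 18354 ± 13225 to 2973 ± 1419 (-2.52 ± 0.41, adjusted p = 2.69e-04), Kitl from 1265 ± 609 to 197 ± 84.9 and Il7 from 56.1 ± 13.3 to 21.6 ± 8.69. Il7 did not pass with quantile normalization (-0.75, adjusted p = 0.104). Clec3b, which encodes tetranectin, fell from 2116 ± 1239 to 14.7 ± 6.91 (-6.97 ± 0.50, adjusted p = 4.86e-07). Fgf3, a fibroblast growth factor gene, rose from 9.42 ± 8.21 to 199 ± 20.4 (4.93 ± 0.79, adjusted p = 2.18e-04).

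Of 14696 genes tested, 10271 passed in limma, 5054 higher and 5217 lower in OBs, and 6009 of the tested genes passed with an absolute log2 fold change of 1 or more. Quantile normalization shifted the median of all genes from 0.0131 to 0.171, with 5830 genes passing higher and 4496 lower. The fold threshold left 2436 higher and 3573 lower. Besides Fgf3, the genes with the largest increase were Nxpe5 (5.47 ± 0.60), Fam110c (5.20 ± 1.16), Lrrn4 (5.16 ± 0.65), Hsh2d (4.78 ± 0.91), A530088E08Rik (4.78 ± 1.03), Mir8113 (4.76 ± 0.97), the guanylate-binding gene Gbp2b (4.74 ± 1.02), Gm13212 (4.49 ± 0.88) and the fucosyltransferase gene Fut7 (4.47 ± 0.56). Inmt, at 0 in all 4 OB libraries, was at least 76.9-fold lower than in MSCs. Besides Clec3b, the others with the largest decrease were Siglech (-6.50 ± 0.94), Col6a6 (-6.31 ± 0.48), the chemokine gene Ccl11 (-6.11 ± 0.68), Tnxb, which encodes tenascin-X (-5.91 ± 0.40), Trhde (-5.78 ± 0.77), the cytokine gene Il33 (-5.72 ± 0.67), Dpt, which encodes dermatopontin (-5.68 ± 0.27), and Vtn, which encodes vitronectin (-5.67 ± 0.73).

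All 36 collagen and matrix genes were lower over all genes and adjusted over the list alone, with a median of -3.25 (camera adjusted p = 6.64e-16, adjusted p = 0.186 with an estimated correlation); Col14a1 changed by -5.29 ± 0.26 and Fbln2 by -5.03 ± 0.13. Of 32 MSC stroma genes, 29 were lower by both counts, with a median of -2.68 (camera adjusted p = 6.37e-09, adjusted p = 0.186 with an estimated correlation), among them Igfbp5 (-4.17 ± 0.26) and the growth factor receptor gene Pdgfra (-4.02 ± 0.22). Of 28 niche factors, 22 were lower and 2 higher by both counts (median -2.51, camera adjusted p = 9.21e-05, adjusted p = 0.186 with an estimated correlation). Igf1 (-3.49 ± 0.17), Lepr (-3.57 ± 0.27), Tnfsf11 (-3.32 ± 0.35) and Csf1 (-2.46 ± 0.17) were lower, and the angiopoietin gene Angpt1 (2.79 ± 0.12) and Tgfb1 (0.86 ± 0.0706) were higher. All 13 mural cell genes were lower (median -3.41, camera adjusted p = 4.27e-04, adjusted p = 0.407 with an estimated correlation), with the pericyte gene Rgs5 at -4.17 ± 0.38.

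Osteoblast and bone matrix genes were lower in the OB libraries, 23 lower and 3 higher of 35 over all genes and adjusted over the list alone (median -1.51, camera adjusted p = 2.19e-04, adjusted p = 0.329 with an estimated correlation). The collagenase gene Mmp13 changed by -3.87 ± 0.34, Col1a1 by -2.32 ± 0.25, Spp1 by -2.03 ± 0.26, Sp7 by -1.70 ± 0.20, Alpl by -1.51 ± 0.19 and Runx2 by -0.77 ± 0.10. Panx3 (2.69 ± 0.75) and Smpd3 (1.33 ± 0.49) rose, and Bglap did not pass (-0.11 ± 0.26, adjusted p = 0.731). With quantile normalization Col1a1 did not pass (-0.42, adjusted p = 0.133). Smpd3 did not pass without wild-type MSC A, B or C or OB A or D (adjusted p from 0.0742 to 0.0902). Cartilage genes went both ways, 9 higher and 5 lower of 20 by both counts (median 0.83, camera adjusted p = 0.684, adjusted p = 0.907 with an estimated correlation): the hedgehog gene Ihh (4.24 ± 1.02) and the hypertrophic cartilage collagen gene Col10a1 (3.38 ± 1.29) rose, and Comp (-2.24 ± 0.22), a cartilage matrix gene, fell. Col10a1 did not pass in 8 of 18 alternatives: edgeR (2.23, adjusted p = 0.118), DESeq2 (2.19, 0.132), or without MSC A (0.0516), B (0.0959) or C (0.0903) or OB A (0.0958), C (0.0543) or D (0.0846). Of the regulators fixed by name, Rest rose (1.36 ± 0.15), Hes1 (-0.94 ± 0.12), Foxo1 (-0.81 ± 0.18) and Runx1 (-0.30 ± 0.0687) fell, and Foxo3 (0.10 ± 0.0880, adjusted p = 0.323) and Flt3l (-0.12 ± 0.27, adjusted p = 0.694) did not pass. Runx1 did not pass with quantile normalization (-0.13, adjusted p = 0.133).

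All 22 erythroid genes were higher in OB libraries (median 1.98, camera adjusted p = 8.75e-07, adjusted p = 0.329 with an estimated correlation), with Hemgn at 2.85 ± 0.27 and the carbonic anhydrase gene Car2 at 2.82 ± 0.19. All 35 cell cycle genes were higher (median 1.94, camera adjusted p = 3.52e-13, adjusted p = 0.186 with an estimated correlation), among them the replication gene Mcm5 (2.44 ± 0.13) and the mitotic checkpoint gene Bub1 (2.45 ± 0.19). Of 82 ribosomal protein genes, 79 were higher and 2 lower (median 1.30, camera adjusted p = 5.37e-25, adjusted p = 0.186 with an estimated correlation), with Rpl32 at 1.71 ± 0.0583. Of 30 immediate early and stress genes, 26 were lower and 3 higher (median -1.36, camera adjusted p = 1.29e-07, adjusted p = 0.186 with an estimated correlation), with Fos at -2.58 ± 0.0953 and the phosphatase gene Dusp1 at -2.61 ± 0.12. The megakaryocyte gene Itga2b (2.36 ± 0.27) rose, and that list did not pass (median 1.60, camera adjusted p = 0.268, adjusted p = 0.746 with an estimated correlation). Interferon-response genes, 19 higher and 4 lower of 30 (median 0.88, camera adjusted p = 0.00372, adjusted p = 0.506 with an estimated correlation), and antigen presentation genes, 9 higher and 0 lower of 16 in limma (median 0.80, camera adjusted p = 0.00720, adjusted p = 0.501 with an estimated correlation), were higher, with the transporter gene Tap1 at 1.98 ± 0.13 and Psmb8 at 2.41 ± 0.20. These counts were the same adjusted over the list alone.

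The test of whether the genotype effect differed between OBs and MSCs used all 16 libraries. Psmb9 had the larger decrease in MSCs: it stood at 181 ± 30.1 in wild-type and 58.0 ± 4.87 in deficient MSCs, and at 639 ± 38.6 and 602 ± 106 in OBs, a difference of effects of 1.51 ± 0.22 on the log2 scale (adjusted p = 0.0423). Lrrc66 was at 0 in all 4 wild-type MSC libraries and at 10.1 ± 5.97 in deficient ones, at least 2.43-fold higher than the mean floor, and went from 24.5 ± 3.0 to 9.67 ± 2.76 in OBs (adjusted p = 0.0423). With the mouse as a replicate block, Psmb9 had an adjusted p of 0.104 and Lrrc66 of 0.149, and the 3 genes that passed shared 0 with these 2. Over all alternatives the adjusted p ranged from 4.47e-06 to 0.198 for Psmb9 and from 0.00702 to 0.198 for Lrrc66.

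Of 15556 genes tested, these 2 passed in limma, and 1786 did at an unadjusted p under 0.05. edgeR called 1 gene and DESeq2 127, of which 40.2% were higher, and quantile normalization gave 3, of which 33.3% were higher, against 50%. The count was 571 without deficient MSC F, 4 without deficient MSC E and 1 without deficient OB E. It was 0 without wild-type MSC B (1724 unadjusted), C (1709) or D (1794), deficient MSC H (1713), wild-type OB A (1500), B (1487), C (1394) or D (1436), or deficient OB F (1308), G (1498) or H (1991). Next by p and not passing were Zhx2 (0.91 ± 0.19, adjusted p = 0.223), C1qtnf6 (1.05 ± 0.22, adjusted p = 0.223), Ttc13 (0.67 ± 0.14, adjusted p = 0.223) and 2700046G09Rik (4.60 ± 0.94, adjusted p = 0.223) upwards, and Cxcl13 (adjusted p = 0.0668), Thsd1 (-1.82 ± 0.32, adjusted p = 0.123), Atg14 (-0.99 ± 0.18, adjusted p = 0.123) and Jade1 (-0.86 ± 0.17, adjusted p = 0.216) downwards. Without deficient MSC F, Zhx2, C1qtnf6, Ttc13, 2700046G09Rik, Thsd1, Atg14 and Jade1 passed (adjusted p from 0.00702 to 0.0267), as did Foxo3, Cd79b, Rpl13, Rpl30, Thy1 and Top2a (0.00702 to 0.0442). So did Thsd1 without wild-type MSC A (0.0292) and 2700046G09Rik without deficient MSC G (0.0189). C1qtnf6 had an adjusted p of 0.0486 with the replicate block (0.00957 to 0.476 over its alternatives).

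Of the lists, B-lineage genes had the largest difference between cell types, positive in all 18 (median 1.35, camera adjusted p = 3.07e-10, adjusted p = 0.135 with an estimated correlation), with 0 over all genes in limma and 7 higher and 0 lower adjusted over the list alone, and fry gave an adjusted p of 0.00842. Rag1 (5.31 ± 1.32, adjusted p = 0.224) and Cd79b (1.27 ± 0.30, adjusted p = 0.223) did not pass. In OB libraries Rag1 lay between 0 and 14.3 normalized counts, close to the floor. Fewer B-lineage cells in the deficient MSC sorts could give the same difference, which was not tested. Ribosomal protein genes had a median of -0.39 (camera adjusted p = 3.84e-35, adjusted p = 0.265 with an estimated correlation), 0 higher and 58 lower adjusted over the list alone and 0 over all genes in limma, with Rpl13 (-0.51 ± 0.11, adjusted p = 0.223) and Rpl30 (-0.58 ± 0.13, adjusted p = 0.223) not passing. Cell cycle genes had a median of 0.34 (camera adjusted p = 2.82e-04, adjusted p = 0.997 with an estimated correlation), with Top2a at 0.85 ± 0.21, adjusted p = 0.223, interferon-response genes of 0.39 (camera adjusted p = 6.29e-04, adjusted p = 0.838 with an estimated correlation), and antigen presentation genes of 0.33 (camera adjusted p = 4.23e-04, adjusted p = 0.838 with an estimated correlation). Secretory pathway genes had a median of 0.20 (camera adjusted p = 6.29e-04, adjusted p = 0.838 with an estimated correlation). MSC stroma genes had a median of 0.49 (camera adjusted p = 0.0312, adjusted p = 0.997 with an estimated correlation), with Thy1 at 1.82 ± 0.40, adjusted p = 0.223. This list was lost without wild-type MSC A (adjusted p = 0.0936) or C (0.12), deficient MSC F (0.0511) or H (0.148), wild-type OB D (0.0759), or deficient OB E (0.215) or F (0.360), a range of 8.58e-08 to 0.360. In all, 7 of 30 lists passed camera, 6 higher and 1 lower, and 11 with the replicate block. With an estimated correlation 0 passed (2 unadjusted), and fry called 2. The number of lists was 11 without wild-type MSC D and 11 without deficient MSC E.

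Of the 20 genes fixed by name, the 19 tested did not pass this test (adjusted p from 0.291 to 0.991). The differences of effects were 1.57 ± 1.05 for Cxcl12, 1.31 ± 0.66 for Il7, 1.36 ± 0.77 for Kitl, 0.16 ± 0.44 for Flt3l, 1.123 ± 0.83 for Tnfsf11, 1.01 ± 0.62 for Igf1, 0.84 ± 0.49 for Csf1 and 1.43 ± 0.84 for Lepr. Bone genes gave -0.29 ± 0.59 for Spp1, 0.28 ± 0.24 for Runx2, 0.0684 ± 0.57 for Sp7, 0.93 ± 1.34 for Bglap, -0.99 ± 0.71 for Col1a1 and -0.53 ± 0.72 for Alpl. The remaining regulators gave -0.17 ± 0.24 for Foxo1, -0.67 ± 0.20 for Foxo3, 0.00800 ± 0.17 for Runx1, -0.24 ± 0.24 for Rest and 0.0506 ± 0.21 for Hes1.

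Genes with a miR-9-5p seed site in the longest annotated 3′ UTR were compared with genes without one, matched on UTR length. In MSCs the 3416 genes with a site differed from 10063 genes without one by a mean log2 fold change of -0.0200, and 1485 genes had no annotated 3′ UTR and were not searched. The exact permutation p was 0.0286, the smallest that 70 relabellings of 8 libraries allow, and 0.171 adjusted over the 6 seed tests. Genes with a site were thus slightly lower, not higher, and 8mer sites alone gave 0.00400 (exact permutation p = 0.914). In OBs the difference was 0.00994 (exact permutation p = 0.514). Without wild-type A, B, C or D, or without deficient E or H, the unadjusted exact permutation p in MSCs was 0.0571 to 0.171. Literature targets of miR-9 did not pass as a list in MSCs (median 0.12, camera adjusted p = 0.261, adjusted p = 0.513 with an estimated correlation) or OBs (median 0.0275, camera adjusted p = 0.0735, adjusted p = 0.544 with an estimated correlation).

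Near Mir9-1, 32 genes within 500 kb were tested. In MSCs 2 of them passed, Bglap and Bglap2, and the other 30 had a median log2 fold change of -0.0361 (0 passing in limma, lowest -1.34, highest 1.19). In OBs 0 passed in limma, and the 30 besides Bglap and Bglap2 had a median of -0.0380.

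X- and Y-linked transcripts were examined as a check of the animals. In MSC libraries, 3 mice (wild-type A and deficient E and F) held more of the Y-linked gene Ddx3y than of Xist, the X-inactivation transcript, and 5 mice held more Xist. All 8 OB libraries held both, with Xist between 3720 and 8053 and Ddx3y between 649 and 1939. Their Xist over Ddx3y was lower in A, E and F (1.92 to 3.99) than in the other mice (9.09 to 12.1). Between genotypes, Xist (-1.18 ± 1.49, adjusted p = 0.669), Ddx3y (1.40 ± 1.61, adjusted p = 0.634), Uty (2.34 ± 1.70, adjusted p = 0.431), Kdm5d (1.03 ± 1.80, adjusted p = 0.764) and Eif2s3y (0.42 ± 1.95, adjusted p = 0.914) did not pass in MSCs. In OBs they gave -0.24 ± 0.27, 0.47 ± 0.30, 0.0271 ± 0.28, -0.0161 ± 0.27 and 0.54 ± 0.20 in that order, and in the test of the difference of effects 0.93 ± 1.76, -0.92 ± 1.90, -2.31 ± 1.97, -1.05 ± 2.10 and 0.12 ± 2.27, with none passing in limma. Between wild-type OBs and MSCs, Uty (3.26 ± 1.29, adjusted p = 0.0419) and Eif2s3y (2.42 ± 0.98, adjusted p = 0.0473) were higher in OBs, and Ddx3y (2.56 ± 1.09, adjusted p = 0.0558), Kdm5d (2.62 ± 1.34, adjusted p = 0.103) and Xist (0.39 ± 1.03, adjusted p = 0.751) did not pass. Neither Uty nor Eif2s3y passed in 10 of 18 alternatives: without a filter (adjusted p = 0.0513 and 0.0564), with edgeR (0.96, adjusted p = 0.434, and 0.74, 0.508), with DESeq2 (0.92 and 0.70, no adjusted p), or without MSC B, C or D or any wild-type OB library (adjusted p up to 0.0933 for Uty and 0.136 for Eif2s3y). Without wild-type MSC A, Ddx3y (3.96, adjusted p = 4.76e-06) and Kdm5d (3.90, adjusted p = 0.00939) passed. With the mouse as a replicate block, Ddx3y (adjusted p = 0.00898) and Kdm5d (adjusted p = 0.0498) passed (over their alternatives 4.76e-06 to 0.778 and 0.00939 to 0.603), and without wild-type MSC A Xist was lower in OBs (-0.970, adjusted p = 4.53e-04; 4.53e-04 to 1.00 over its alternatives).

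**Figure D3:**
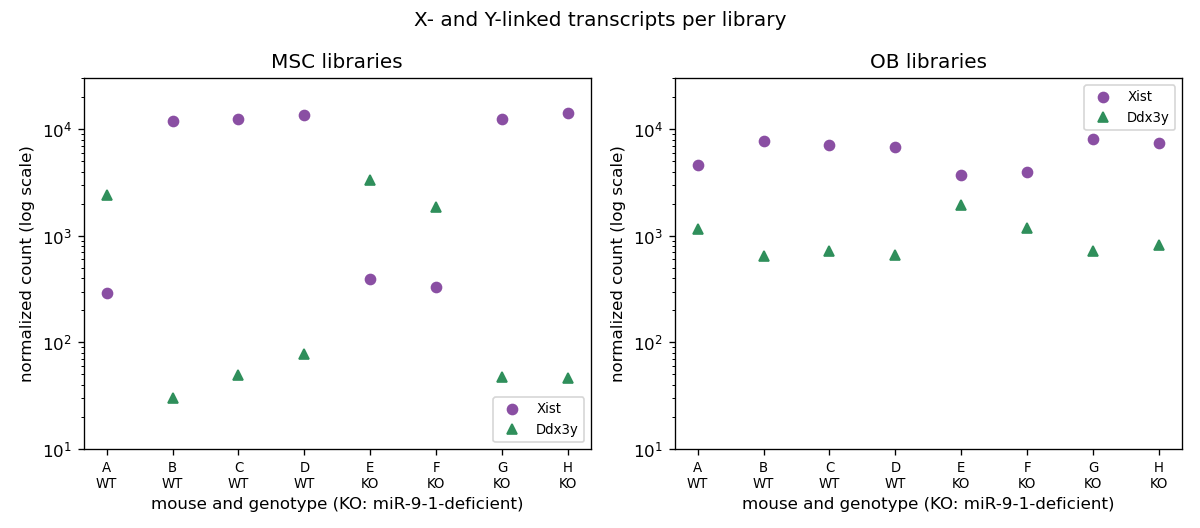
Normalized counts of Xist (circles) and Ddx3y (triangles) on a log axis in each mouse, MSC libraries on the left and OB libraries on the right. In OB libraries Xist lies between 3720 and 8053 in every mouse, and in MSC libraries it lies between 291 and 392 in 3 mice.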

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

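Tests chosen only after the result was seen were the 3 on the sex-linked and progenitor genes, the one on the neighbourhood of Mir9-1, the 3 on the smaller number of genes in OBs, the comparison with splits that part each mouse, and the Y-linked and muscle covariates; the blood-cell test and the 35 splits were chosen before.

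All 8 OB libraries hold Xist and Ddx3y together, and genes of blood progenitors at similar levels, while each MSC library holds mostly 1 of the 2 sex-linked transcripts. In OB libraries Xist over Ddx3y was lower in A, E and F (3.99, 1.92 and 3.35) than in the other mice (9.09 to 12.1). The OB libraries thus still followed, in part, the MSC library of their mouse. Each mouse's own blood-forming cells are argued against as the only source. In mice whose MSC library is low in Xist, the OB library of the same mouse held at least 9.49 times as much. Reads passed over from the MSC libraries are argued against for the progenitor genes alone. There the lowest OB library exceeded the highest MSC library by a median factor of 3.10 over 22 genes (19 of 22 above every MSC library). For Xist and Ddx3y this cannot decide, since the highest OB values (8053 and 1939) lay below the highest MSC values (14158 and 3355). Passing of reads between OB libraries was not tested. The median coefficient of variation of the progenitor genes over OB libraries was 10.1%, against 53.9% for MSC stroma genes. The stroma value includes the high levels of that list in deficient E and F. Over all genes tested in both cell types, the median within-group SD in OBs was 0.178 on the log2 scale. Low variation was thus common among genes in OB libraries and does not single out a shared source. A common mixed-sex source of RNA is a candidate explanation and stays open, with no sort gate in the labels.

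Osteoblast and bone matrix genes were lower in deficient MSCs by a median of -0.95. The median was -0.94 with the Y-linked level as a covariate (-1.18 to -0.72 with a library left out). It was -0.93 for genes outside the window around Mir9-1 (-1.08 to -0.66). The values with the Y-linked covariate argue against unequal sexes as the whole cause. Bglap and Bglap2 lie in the window, and leaving them out of 34 genes could hardly move a median. The value outside the window shows only that the decrease was not limited to genes near Mir9-1. With the blood-cell level the median was -0.96 (-1.22 to -0.69). That covariate left the B-lineage median at -1.58, against -1.65 without it, so it cannot decide on blood cells in the wild-type sorts. With the muscle level as a covariate the bone matrix median was -0.90, although single genes no longer passed. An effect of genotype may remain, as a hypothesis, and age and the cell mix within the gate stay untested.

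Fewer genes passed in OBs (4) than in MSCs (159), a gap that rests on single libraries: in limma, without A to H in turn, 12, 0 (2731 unadjusted), 6, 1, 11, 2261, 1 and 2 genes passed in MSCs and 3, 3, 7, 3, 20, 30, 3 and 108 in OBs, and with the series of animal numbers 8 and 9. Over the 13863 genes tested in both, a larger spread between OB libraries is argued against, with a median within-group SD in OBs 0.537 times that in MSCs (0.480 to 0.588 with a library left out). For the 149 genes that passed in MSCs and not in OBs it was 1.26 times (0.862 to 1.51), which cannot be told apart from their choice by passing in MSCs, as the 152 genes with the largest MSC fold gave 0.571 and bone matrix genes 1.46. Among genes that passed in MSCs, the OB change in the MSC direction was a median 1.22 for 29 genes at least 8-fold below their MSC level. It was 0.117 for 27 genes at or above it, a difference of 1.099. The OB changes were not scaled by the MSC fold of each gene. The wild-type OB libraries also entered both the grouping and the change. This difference therefore cannot decide on dilution by RNA shared between OB libraries. Dilution and a larger spread of these genes stay open, beside a smaller biological effect.

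For the counts of passing genes in MSCs and in OBs, 1 of the 35 splits of the samples, the real one, gave as many. This is the smallest share that 35 splits allow (2.86%), without adjustment over the 4 comparisons. Chance is argued against for these counts but not excluded. The real counts and highest others were 159 and 0 in MSCs and 4 and 1 in OBs. Between cell types the real count was 10271 and the highest other 0, with 1 of 35 splits giving as many. Of these 35, 8 part each mouse's libraries as the real one does, too few for a share under 0.05, and the others keep both libraries of some mice together. For the difference of effects 1 of 35 splits gave as many, with a real count of 2 and a highest other of 1. That fit ignores the pairing by mouse, and its count was 0 in limma with a pseudocount of 5 (1833 unadjusted) and in 11 of 16 fits with 1 library left out (1308 to 1991 unadjusted). With the mouse as a replicate block, 3 genes passed and shared 0 with the 2.

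Of 489 sets of 4 libraries, 28 held a library far from the other 3 by Dixon's test, where about 24.4 come by chance. In MSCs of wild-type mice these were D for Csf1 (1629), Rest (917), Smpd3 (2242), the Rn45s share (2.46%) and the mean log2 levels of cartilage genes (12.3) and Wnt targets (8.47), A for Xist (291) and Atg14 (214), and B for BMP and TGF-beta targets (10.95). In deficient MSCs they were F for Inmt (398) and Rps27 (3637), E for Cpz (97.4), G for 2700046G09Rik (7.84) and megakaryocyte genes (8.17), and H for Lrrc66 (19.0). In wild-type OBs they were D for Penk (49.2) and Tnxb (104), A for Ddx3y (1167), B for Fbln2 (210.05), Hspa1a (700.4) and macrophage genes (7.23), and C for Rpl13 (6852). In deficient OBs they were F for Cxcl13 (3.26), Il7 (69.7) and Runx2 (2060.1), and E for Thy1 (356), Cirbp (889.7) and oxidative phosphorylation genes (9.45).

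Psmb9 (1.51) and Lrrc66 (-4.63) passed the test of the difference of effects, though not with the mouse as a replicate block. The size for Lrrc66 is set by the value added before the log, since its wild-type MSC libraries held 0, and was -2.54 with a pseudocount of 5. It differed by camera for MSC stroma genes (median 0.49), B-lineage genes (1.35), cell cycle genes (0.34), interferon-response genes (0.39), secretory pathway genes (0.20), ribosomal protein genes (-0.39) and antigen presentation genes (0.33), all lost with an estimated correlation (smallest adjusted p = 0.135).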

How the results depend on the processing

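The Y-linked, muscle and stromal alternatives, the libraries left out for lists, seed sites and the correlation, and the lists with the block were chosen after seeing the data. The cause of each change below was not tested. For MSC genes the count was 1714 with array weights, 1196 with DESeq2, 42 with the blood-cell covariate, 2251 with all 16 libraries in 1 fit, 2271 with the mouse as a random term, 8 with the series of animal numbers, 73 with the Y-linked covariate, 0 with the muscle covariate (limma, 2725 unadjusted), 0 without both high-muscle libraries (1942 unadjusted), and 0 to 2261 with 1 library left out. For OB genes it was 16 with quantile normalization, 75 with array weights, 194 with DESeq2, 10 with the blood-cell covariate, 23 with all 16 libraries, 43 with the random term, 9 with the series, 65 with the Y-linked covariate, 252 with the stromal covariate, 88 without both high-stroma libraries, and 3 to 108 with 1 left out. Between cell types it was 6009 at an absolute log2 fold change of 1 or more. For the difference of effects it was 0 with a pseudocount of 5 (limma, 1833 unadjusted), 4 without a filter, 1 with a filter of 50, 140 with array weights, 1 with edgeR, 127 with DESeq2, 0 with the blood-cell covariate (1939 unadjusted), 1 with the Y-linked covariate, and 0 to 571 with 1 left out. With the mouse as a replicate block, 3 genes passed for the difference of effects and 10216 between cell types (10026 shared); beyond Psmb9, Lrrc66, C1qtnf6, Ddx3y, Kdm5d and the 11 lists for the difference of effects, the block changed no other call of a named gene.

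The number of lists with an estimated correlation was 0 in every comparison, and with fry 3 in MSCs, 0 in OBs and 2 for the difference of effects; with the replicate block it was 11 for the difference of effects. With 1 library left out it ran from 7 to 20 in OBs and from 6 to 11 for the difference of effects. The seed-site difference in MSCs was 0.00400 for 8mers, 0.0179 for miR-9-3p sites and -0.0254 to -0.0121 with 1 left out. The correlation of effects ran from 0.409 to 0.542 with 1 mouse left out.

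The values that follow are log2 fold changes with a sign opposite to the reported one. In MSCs: with array weights, Ddx3y -0.16, Xist 0.27, Eif2s3y -2.0; with edgeR, Hes1 0.00953; with DESeq2, Hes1 0.0136; with the blood-cell covariate, Uty -0.22, Ddx3y -1.18, Xist 1.05, Kdm5d -1.79, Rest -0.0890, Eif2s3y -2.83, Hes1 0.0127; with the Y-linked covariate, Kdm5d -0.29, Eif2s3y -1.01, Hes1 0.00207; with the muscle covariate, Hes1 0.00716; with both high-muscle libraries left out, Hes1 0.0813. In OBs: with array weights, Xist 0.0505, Hes1 -0.0492, Uty -0.26; with edgeR, Kdm5d 0.0684; with DESeq2, Kdm5d 0.0631; with the blood-cell covariate, Flt3l 0.0120, Uty -0.22; with the Y-linked covariate, Hes1 -0.0220, Foxo1 -0.00210, Uty -0.15; with the stromal covariate, Hes1 -0.0166, Foxo1 -8.37e-04, Uty -0.0981; with both high-stroma libraries left out, Lepr -0.23, Csf1 -0.13, Ddx3y -0.0178, Spp1 -0.11, Cxcl12 -0.30, Tnfsf11 -0.65, Xist 0.26, Il7 -0.0925, Hes1 -0.18, Foxo1 -0.0267, Uty -0.46. Between cell types: with quantile normalization, Flt3l 0.0288; with edgeR, Xist -0.49; with DESeq2, Xist -0.53; with the blood-cell covariate, Bglap 0.0228. For the difference of effects: with a pseudocount of 5, Eif2s3y -0.19; with quantile normalization, Spp1 0.0136; with array weights, Xist -0.12, Ddx3y 0.19, Hes1 -0.0199, Sp7 -0.16, Runx1 -0.0621; with edgeR, Eif2s3y -1.07, Runx1 -0.0109; with DESeq2, Eif2s3y -1.1, Runx1 -0.0159; with the blood-cell covariate, Xist -0.15, Kdm5d 0.30, Ddx3y 0.33. With 1 library left out, the range crossed 0 in MSCs for Eif2s3y -0.97 to 2.04, Hes1 -0.11 to 0.11, Cxcl12 -0.74 to 0.0252, Kdm5d -0.50 to 2.32, Runx1 -0.0228 to 0.19. It did so in OBs for Kdm5d -0.18 to 0.18, Uty -0.20 to 0.20, Foxo1 -0.0333 to 0.0971, Hes1 -0.0308 to 0.13, Il7 -0.0376 to 0.61, between cell types for Flt3l -0.37 to 0.0450, Xist -0.97 to 0.87, Bglap -0.28 to 0.14, and for the difference of effects for Flt3l -0.0630 to 0.40, Eif2s3y -1.50 to 1.51, Hes1 -0.0658 to 0.16, Runx1 -0.0826 to 0.13, Kdm5d -2.33 to 0.48, Sp7 -0.22 to 0.46, Ddx3y -2.32 to 0.17, Alpl -0.98 to 0.0749, Spp1 -0.69 to 0.17. Over all alternatives of the named genes, the call and direction held for 1089 of 1640 values in MSCs (480 weaker, 43 stronger, 28 reversed), 761 of 892 in OBs (7, 86 and 38), 1156 of 1214 between cell types (41, 8 and 9) and 958 of 1073 for the difference of effects (32, 40 and 43).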

Other observations

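The lists of glucocorticoid-responsive genes and FoxO targets were chosen after the first MSC results were seen and before their own genes were tested. In deficient MSCs, 17 glucocorticoid-responsive genes other than Fkbp5, Zbtb16, Klf15 and Slc10a6 were higher than all genes by a mean of 1.09 on the log2 scale (exact permutation p = 0.0286, the smallest these can give, adjusted p = 0.0381; 0.90 to 1.28 with a library left out), with 15 of 17 positive, 1 passing over all genes and 12 adjusted over the list alone. In OBs 16 of them gave 0.79 (exact permutation p = 0.0286), with 0 passing over all genes in limma (7 unadjusted) and 5 adjusted over the list alone. The list was chosen because Fkbp5, Zbtb16, Klf15 and Slc10a6 had risen in these same MSC libraries. Genes that vary together with them would follow the same split, so these p-values are not an independent test. The OB libraries carry the same animal numbers and are not a second test. A glucocorticoid-like response may go with the deficiency, as a hypothesis, since handling and hormone levels were not recorded. Of the 17 genes, 3 are in other lists. FoxO targets gave 0.79 in MSCs (15 genes, 13 positive, exact permutation p = 0.114; 0.56 to 1.04) and 0.37 in OBs (exact permutation p = 0.0286, adjusted p = 0.0381), so a rise of FoxO targets in MSCs cannot be told apart from no rise with 4 mice per group. Over all genes 0 FoxO targets passed in limma in MSCs (7 unadjusted) or OBs (3 unadjusted), and adjusted over the list alone 4 and 0 did.

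Lists that passed in deficient OBs beyond those in the report had medians from -0.49 to 0.17. Neutrophil genes gave -0.49 (camera adjusted p = 1.89e-04, adjusted p = 0.594 with an estimated correlation; lost without wild-type B, adjusted p = 0.193, range 4.18e-09 to 0.193), interferon-response genes -0.13 (camera adjusted p = 0.00367, adjusted p = 0.544 with an estimated correlation), secretory pathway genes -0.12 (camera adjusted p = 0.00367, adjusted p = 0.544 with an estimated correlation) and B-lineage genes -0.36 (camera adjusted p = 0.0230, adjusted p = 0.544 with an estimated correlation; lost without wild-type C, 0.0810, or deficient F, 0.0781, range 0.0144 to 0.0810). The B-lineage median was -0.18 with array weights, -0.19 with a filter of 50 and -0.21 without both E and F, with 9 of 15 genes negative against 13 of 15. Antigen presentation genes gave -0.11 (camera adjusted p = 0.0177, adjusted p = 0.705 with an estimated correlation; lost without wild-type C, 0.1003, or deficient E, 0.298, range 9.3e-04 to 0.298) and Notch genes 0.17 (camera adjusted p = 0.0251, adjusted p = 0.544 with an estimated correlation; lost without wild-type B, 0.0740, C, 0.0551, or D, 0.0609, or deficient E, 0.321, range 0.00912 to 0.321). Hypoxia and glycolysis genes gave -0.11 (camera adjusted p = 0.0391, adjusted p = 0.544 with an estimated correlation; lost without wild-type C, 0.0705, or D, 0.184, or deficient F, 0.0701, G, 0.0533, or H, 0.0608, range 0.00848 to 0.184) and T and NK genes -0.23 (camera adjusted p = 0.0469, adjusted p = 0.544 with an estimated correlation; lost without wild-type B, 0.215, or C, 0.142, or deficient E, 0.166, or G, 0.0842, range 0.0243 to 0.215).

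Between wild-type OBs and MSCs, Wnt targets (-2.45, camera adjusted p = 1.77e-04, adjusted p = 0.186 with an estimated correlation), BMP and TGF-beta targets (-2.12, camera adjusted p = 0.00146, adjusted p = 0.186 with an estimated correlation), Notch genes (-1.07, camera adjusted p = 0.0102, adjusted p = 0.329 with an estimated correlation), secretory pathway genes (-0.50, camera adjusted p = 0.00188, adjusted p = 0.186 with an estimated correlation) and literature targets of miR-9 (-0.94, camera adjusted p = 0.0107, adjusted p = 0.186 with an estimated correlation) were lower in OBs. Oxidative phosphorylation genes were higher (0.23, camera adjusted p = 0.0150, adjusted p = 0.186 with an estimated correlation). Inflammatory genes (-1.57, camera adjusted p = 0.0428, adjusted p = 0.557 with an estimated correlation) were lower, but not without wild-type MSC B (0.0560) or C (0.0884) or OB D (0.0565), range 0.0115 to 0.0884. Neutrophil genes, among them Camp (-4.01 ± 0.80) and Ltf (-3.46 ± 0.58), were lower (-2.80, camera adjusted p = 0.0476, adjusted p = 0.746 with an estimated correlation), but not without wild-type MSC A (0.0505), B (0.0872) or C (0.0795) or OB A (0.0742), C (0.0601) or D (0.0663), range 0.00194 to 0.0872. In all, 19 of 30 lists passed camera, 6 higher and 13 lower; with an estimated correlation 0 passed (6 unadjusted), and fry called 23.

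Inflammatory genes in MSCs had a negative median (-0.14) and mean (-0.25) while camera, which compares the test statistics of the list with those of all other genes, gave a positive direction that did not pass (camera adjusted p = 0.792, adjusted p = 0.937 with an estimated correlation).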
